A study of Mus musculus with 46 samples.

How the data were processed

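RNA sequencing was analysed from 46 libraries in 4 tables that cover 13 groups. A first table held 18 AML12 libraries with a doxycycline-inducible hairpin, in 6 groups of 3. A second table held 9 AML12 libraries with conventional hairpins, in 3 groups of 3. The remaining tables held liver libraries, 4 control and 4 Falcor knockout livers on the diet labelled NCD, and 5 control and 6 knockout livers on the diet labelled HFD. Groups were taken from the sample titles and characteristics. Of the liver control columns, 4 carried a bare name that also matched the label of a cell line library, so they were assigned to their group without a replicate number and are named by column (Ctrl-1, Ctrl-2, Ctrl-3).

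The libraries were strand-specific and depleted of ribosomal RNA, per the labels' protocols. The submitters' processing notes name kallisto, DESeq2 and the mouse build mm10, without versions or the role of each tool. The annotation release and the settings of the authors' counting are not given in the sources used here. The table of conventional hairpins holds deposited counts, whole numbers per gene that summed to 4474760 to 8837581 per library. Between replicates of that table the group medians of variance over mean were 1.94 to 2.40, above counting noise. The other 3 tables hold deposited values that were treated as a score. They are whole numbers whose columns sum to 859568 to 883564 for the inducible lines, 833910 to 872375 for NCD and 918867 to 975752 for HFD. Their variance over mean was 0.0385 to 0.160 in the inducible lines and 0.193 to 0.220 in NCD, below counting noise, and 0.796 to 1.21 in HFD. Across 7335 genes, the log2 ratio of the count table to the inducible table rose with log2 transcript length at a slope of 1.30 (r = 0.68, across genes). Those values therefore look like a length-scaled, rounded unit such as TPM, although no source says so. Sequencing depth is unknown for these 3 tables. Rounding to whole numbers also makes the spread of low values too small, because replicates can share 1 value. A set of 3 rows with identical values held 22.4 to 78.2% of each HFD column, against 3.43 to 12.9% of each NCD column, which makes scaling between libraries matter more there.

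The test planned for every table was a count model. The 3 score tables do not carry counts, so limma-trend was used for them in its place. Values were divided by trimmed mean of M-values (TMM) scale factors, and log2(value + 1) was fitted for genes with a mean value of at least 3. Moderated tests used a mean-variance trend and robust estimation. Fold changes from these tables are on the log2(value + 1) scale, which understates the change of low genes. The counts were tested with edgeR's quasi-likelihood test after filterByExpr and TMM scaling, with robust estimation, and values are printed as CPM, counts scaled to a common library size. All groups of 1 table shared 1 fit. P-values were adjusted by the Benjamini-Hochberg method over the genes of each comparison, and genes with an adjusted p below 0.05 were called. No scaling or test joined libraries of different tables. The planned joint fit of both diets needs counts. It was replaced by the difference of the 2 within-table estimates, tested on their moderated standard errors with Welch-Satterthwaite degrees of freedom. The sources do not say whether replicates came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

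Before the data were examined, 35 gene lists, the groups, the planned tests, a first set of alternatives and the rule for named genes were fixed. The limma-trend fit of the score tables and further alternatives were chosen afterwards. Falcor, its neighbour Foxa2 and Zc3h11a were always named. Further genes were taken from those called in a comparison, with a mean of at least 5 in the higher group, a symbol other than a predicted gene, clone or pseudogene name, and no overlap between the groups compared. Of these, the 8 with the largest positive and the 8 with the largest negative fold change could be named, and up to 4 members with the smallest p of each list described. The overlap condition did not apply to differences between comparisons. A few genes that the rule named are not reported here, although they stay in the counts and list tests. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run as alternatives. Overlaps of called genes were set against the count that independent lists would share, with a hypergeometric p. The 2 conventional knockdowns share their controls, so unchanged groups and their shared controls, all drawn from the control means, were simulated 50 times.

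The models were tested on simulated data with 200 changed genes per table. Of genes changed 2-fold, 92.5% were recovered in the inducible table, 73.1% in the conventional table, 55.2% in NCD and 64.2% in HFD. At 1.5-fold the shares were 82.1%, 38.8%, 26.9% and 35.8%, so smaller differences would often be missed in the livers. Among genes with a mean of at least 50, the median coefficient of variation within a group was 2.06 to 7.06% in the inducible lines, 5.39 to 6.36% in the conventional lines and 8.89 to 13.2% in liver. Replicates within a group differed from each other, with correlations of 0.905 to 0.992 across genes, and none was counted as a duplicate.

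The alternatives were another scaling (DESeq2's size factors, or none), other filters, other pseudocounts (0.5 and 5), non-robust estimation, library weights, the replicate number as a block, only the groups of the comparison, a DESeq2 Wald test for the counts, and each library left out in turn. Coordinates and transcript lengths came from the GENCODE M21 annotation of the same build, in which 90.8% of the symbols of the score tables and 89.1% of those of the count table were found. Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.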

Results

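Gene expression was measured by RNA sequencing in 27 libraries of AML12, a mouse hepatocyte cell line, and in 19 libraries of mouse liver. The series addressed what the long noncoding RNA Falcor does in nuclear speckles, the splicing factor-rich bodies of the nucleus. It also asked whether Falcor and ZC3H11A, a zinc finger protein of the mRNA export machinery, act on the same genes, and what the loss of Falcor does in liver in a normal and in a disease setting, here the diets labelled NCD and HFD. In the first experiment, AML12 lines with an inducible control hairpin (shCtrl) or an inducible hairpin labelled shLinc, taken here as the Falcor hairpin from the characteristics' tag, were sampled without doxycycline, with doxycycline, and in a state labelled restored (3 libraries per group). In the second, AML12 cells carried a conventional control, Falcor or ZC3H11A hairpin (3 libraries each). Control and Falcor knockout livers numbered 4 and 4 on NCD and 5 and 6 on HFD. Total counts were 4474760 to 8837581 per library for the conventional hairpins, and depth is unknown for the other tables.

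Falcor is listed as 9030622O22Rik (ENSMUSG00000086141.7), a long intergenic noncoding RNA gene of 3 annotated transcripts on the minus strand of chromosome 2, at 147944740 to 148040203 in the mm10 build. Foxa2 (ENSMUSG00000037025.11), which encodes a forkhead transcription factor of hepatocytes, lies at 148042877 to 148046969 on the same strand, 2673 bp away, with 0 annotated genes between them. Zc3h11a lies on the minus strand of chromosome 1 at 133619862 to 133661380 (ENSMUSG00000102976.6), where 2 overlapping gene models share the symbol, so its values can include reads of both.

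In the inducible lines Falcor was low. The control hairpin libraries held values of 4 to 6 in all 3 states. The Falcor hairpin libraries held 12, 9 and 10 without doxycycline, 2, 2 and 3 with it, and 11, 9 and 11 in the restored state. With doxycycline, Falcor was at 2.45 ± 0.594 in the Falcor hairpin line against 4.90 ± 0.604 in the control line (scaled values, mean ± SD, n = 3 each; log2 fold change −0.78 ± 0.14 SE, limma adjusted p = 2.18e-04). Without doxycycline it was higher in the Falcor hairpin line than in the control line (log2 fold change 0.75 ± 0.14, limma adjusted p = 1.88e-04), and so it was in the restored state (0.86 ± 0.14, adjusted p = 6.40e-05). In the conventional experiment the control libraries held 38, 11 and 24 Falcor counts, the Falcor hairpin libraries 7, 4 and 5, and the ZC3H11A hairpin libraries 4, 3 and 6. Falcor fell under both hairpins, by 2.07 ± 0.51 and 2.17 ± 0.52 on the log2 scale (edgeR adjusted p = 0.00242 and 0.00226). Zc3h11a fell to 8.24 ± 5.15 CPM under its own hairpin from 63.6 ± 4.36 CPM in controls (log2 fold change −3.03 ± 0.29, edgeR adjusted p = 2.03e-05). In liver, the 4 NCD controls held Falcor values of 70, 115, 117 and 135 and the 5 HFD controls 26, 17, 24, 27 and 24, whereas Falcor was listed at 0 in each of the 10 knockout livers (limma adjusted p = 1.91e-07 for NCD and 3.60e-09 for HFD).

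**Figure D1:**
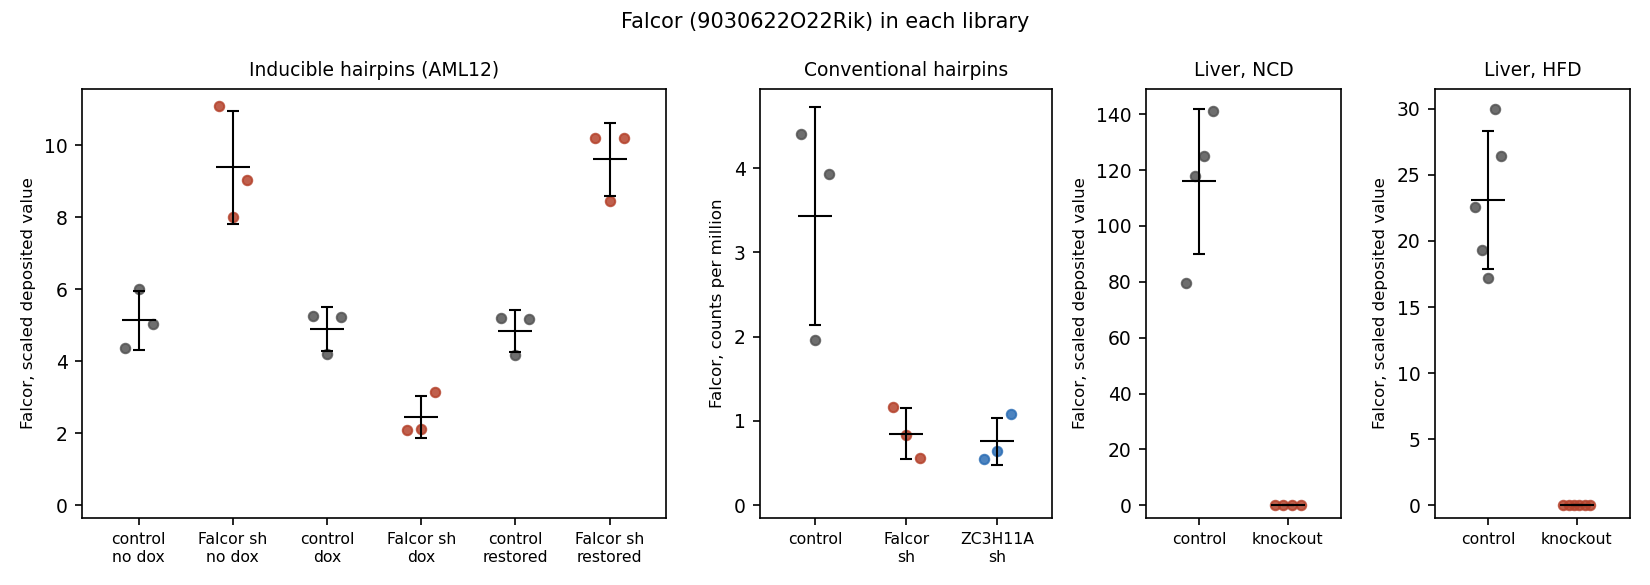
Falcor (9030622O22Rik) in each library, as scaled values for the inducible lines and both liver tables and as CPM for the conventional hairpins, with points for libraries and bars for the mean ± SD of a group. The Falcor hairpin line lies below the control line only with doxycycline, at 2.45 against 4.90, and the knockout livers lie at 0.

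The comparison of both hairpins under doxycycline asked what changes in hepatocytes when Falcor is depleted. It also holds differences that the lines had before doxycycline, which are given below for some of the genes only. For the others, such as Alb, Hpx, Ttr, Rbp4, Egr1 and Fos, the untreated hairpin difference is not given. Their values here alone do not show whether a difference arose with doxycycline. Albumin mRNA was at 34.4 ± 1.47 against 93.7 ± 2.06 in the control line (Alb, log2 fold change −1.42 ± 0.04), and Hpx, which encodes the heme scavenger hemopexin, Ttr, which encodes transthyretin, and Rbp4, which encodes a retinol carrier, fell by 0.80, 0.68 and 0.43. The growth-response transcription factor gene Egr1 was at 168 against 60.1 (1.47 ± 0.04) and Fos, another, at 13.7 ± 1.13 against 3.85 ± 0.605. The largest increase was that of Lcn2, the iron-scavenging acute phase protein lipocalin 2, at 84.2 ± 1.39 against 9.44 ± 0.0218 (log2 fold change 3.03 ± 0.03). Lcn2 was also among the large increases without doxycycline, given below. The largest decreases were those of Isg20, an interferon-induced exonuclease (8.42 against 72.0 ± 5.54), and Atp5g1, a subunit of the mitochondrial ATP synthase (38.6 ± 3.83 against 252 ± 10.4).

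Of 9877 genes tested, 5172 were called by limma, 2507 higher and 2665 lower, with a median absolute log2 fold change of 0.336. Beyond Lcn2, Fos and Egr1, the largest increases included Marcksl1 (1.98 ± 0.07), Tlcd3a (1.72), the aldose reductase family member Akr1b7 (1.42), Depp1 (1.36) and the neutrophil chemokine Cxcl5 (1.35). Akr1b7 and Cxcl5 were higher by more without doxycycline, as given below, so their differences here did not arise with doxycycline. The largest decreases included the aspartoacylase gene Aspa (−1.89), the prolactin family gene Prl2c2 (−1.82), Tspan17 (−1.70), Tbc1d8b (−1.68), Xlr (−1.56) and Mab21l4 (−1.56). Foxa2 rose slightly (0.17 ± 0.03, adjusted p = 4.74e-04) and Zc3h11a fell (−0.38 ± 0.07, adjusted p = 1.37e-04). Several of these replicates share 1 rounded value, so their errors are too small for low genes.

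Among hepatocyte secreted proteins, 6 of 8 tested members fell and none rose over all genes (6 lower and 1 higher when adjusted over the list alone; median −0.72, camera adjusted p = 0.00491, and adjusted p = 0.0772 with an estimated correlation). Cholesterol synthesis and uptake genes were mixed, with 14 of 25 higher and 3 lower (15 and 4 adjusted over the list alone). The squalene synthase gene Fdft1 rose by 0.51, while Idi1 fell by 0.56 (list median 0.21, camera adjusted p = 0.00461, and adjusted p = 0.0878 with an estimated correlation). Of 13 immediate early genes, 7 rose, among them Jun (0.53) and Ier2 (0.60), and 2 fell, the same counts when adjusted over the list alone (median 0.33, camera adjusted p = 0.0328, and adjusted p = 0.0878 with an estimated correlation). Of 21 fatty acid oxidation and PPARα target genes, 10 fell and 4 rose (11 and 4 adjusted over the list alone). Hadhb, of the mitochondrial trifunctional protein, fell by 0.68, Plin2 by 0.35 and Angptl4, an inhibitor of lipoprotein lipase, by 1.11, while the acyl-CoA thioesterase Acot1 rose by 0.38 (median −0.19, camera adjusted p = 0.0353, and adjusted p = 0.0878 with an estimated correlation).

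The nuclear speckle and splicing factor list moved both ways, with 12 of 33 members higher and 8 lower (13 and 10 adjusted over the list alone; median 0.13, camera adjusted p = 0.359). U2af2, which recognises the polypyrimidine tract, rose by 0.46, Snrnp70, of the U1 particle, by 0.38 and Sart1 by 0.28, and Sf3b1, of the U2 particle, fell by 0.53. Of 15 genes of the TREX mRNA export complex, 7 rose and 3 fell, the same when adjusted over the list alone (median 0.03, camera adjusted p = 0.359). Its helicase Ddx39b rose by 0.53, Thoc5 by 0.33 and the export cofactor Nxt1 by 0.28.

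The same hairpin comparison without doxycycline asked whether the lines differed before induction, and in the restored state whether the difference returned. The lines differed widely in both. Without doxycycline, the Falcor hairpin line had less of the stress-induced transcription factor gene Atf5 (113 ± 0.801 against 311 ± 12.9) and of the asparagine synthetase gene Asns (104 ± 3.16 against 260 ± 2.65), and lower Mthfd2 and Shmt2 of mitochondrial folate metabolism (−1.87 ± 0.04 and −1.37 ± 0.03). It had more of Pdk4, which shuts down pyruvate oxidation (52.3 ± 0.391 against 9.99 ± 0.116). In the restored state it had less of Ccn2, the matricellular YAP target (136 ± 1.91 against 768 ± 8.54, −2.49 ± 0.03), and more of angiotensinogen mRNA (Agt, 64.1 against 7.97, 2.86 ± 0.08).

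Without doxycycline limma called 6445 genes (2978 higher, 3467 lower). Olfm4 was listed at 0 in the 3 control libraries and had a mean of 18.1 in the Falcor hairpin line. The other large increases were those of Akr1b7 (4.15 ± 0.07), Cxcl5 (2.96), Tnfaip2 (2.68), Lcn2 (2.67), Ppp1r1b (2.61) and the granulocyte growth factor Csf3 (2.58). The largest decreases were those of Cth, which makes cysteine (−2.38 ± 0.08), the pseudokinase Trib3 (−2.29 ± 0.07), Trgc4 (−2.24), Mirt1 (−2.12), the small nucleolar RNA Snora73b (−2.04, and −1.42 with its call lost at adjusted p = 0.0625 without untreated Falcor hairpin replicate 2), Chac1 (−2.02) and Etv4 (−1.99). Foxa2 was lower (−0.14 ± 0.03, adjusted p = 0.00180), but 0.05 higher with no rescaling between libraries, and Zc3h11a was at −0.07 (adjusted p = 0.389). Of 17 ATF4 targets, 16 fell and none rose, also when adjusted over the list alone (median −1.13, camera adjusted p = 1.84e-08, and adjusted p = 0.00631 with an estimated correlation). Proliferation genes fell in 19 of 23 cases and rose in none (19 and 1 adjusted over the list alone; median −0.62, camera adjusted p = 1.65e-06, and adjusted p = 0.00631 with an estimated correlation), led by the replication genes Mcm5 (−1.02), Mcm3 (−1.08), Mcm2 (−1.05) and Pcna (−0.82). Fatty acid oxidation and PPARα targets rose in 17 of 21 cases and fell in 1, the same when adjusted over the list alone (median 0.41, camera adjusted p = 2.75e-05, and adjusted p = 0.00625 with an estimated correlation), among them Acot1 (0.88) and the dehydrogenase gene Acadm (0.74).

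In the restored state limma called 5718 genes (2543 higher, 3175 lower). Beyond Agt, the increases were led by Ppp1r1b (2.75), Mmp7 (2.50), the epithelial transcription factor Ehf (2.44), Pdcd4 (2.15), Ndrg2 (2.05), Sema4g (2.03) and Txnip (1.96), and beyond Ccn2 the decreases by Tigit (−2.47), Mettl7b (−2.44), Adam8 (−2.22), Tnnt2 (−2.14), Fosl1 (−2.10) and Gcnt3 (−2.08). Foxa2 (0.07, adjusted p = 0.0942) and Zc3h11a (0.12, adjusted p = 0.122) did not pass. All 17 ATF4 targets tested fell, also when adjusted over the list alone (median −0.87, camera adjusted p = 1.22e-11, and adjusted p = 0.00341 with an estimated correlation), with Shmt2 at −1.04 and Asns at −0.94. Cholesterol genes fell in 24 of 25 cases and rose in none, also when adjusted over the list alone (median −0.47, camera adjusted p = 3.98e-10, and adjusted p = 0.00477 with an estimated correlation), with Cyp51, Msmo1, Fdps and Lss lower by 0.72 to 0.94. Of 11 acute phase genes, 9 rose and none fell, also when adjusted over the list alone (median 0.55, camera adjusted p = 6.33e-04, and adjusted p = 0.00914 with an estimated correlation), with Hp at 1.53, Lcn2 at 1.49, Lbp at 0.75 and Stat3 at 0.55. Across genes, which are not independent replicates, the untreated and restored fold changes correlated at r = 0.74, and 4504 genes were called in the same direction in both against 1881 from independent lists and 182 in opposite directions.

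**Figure D2:**
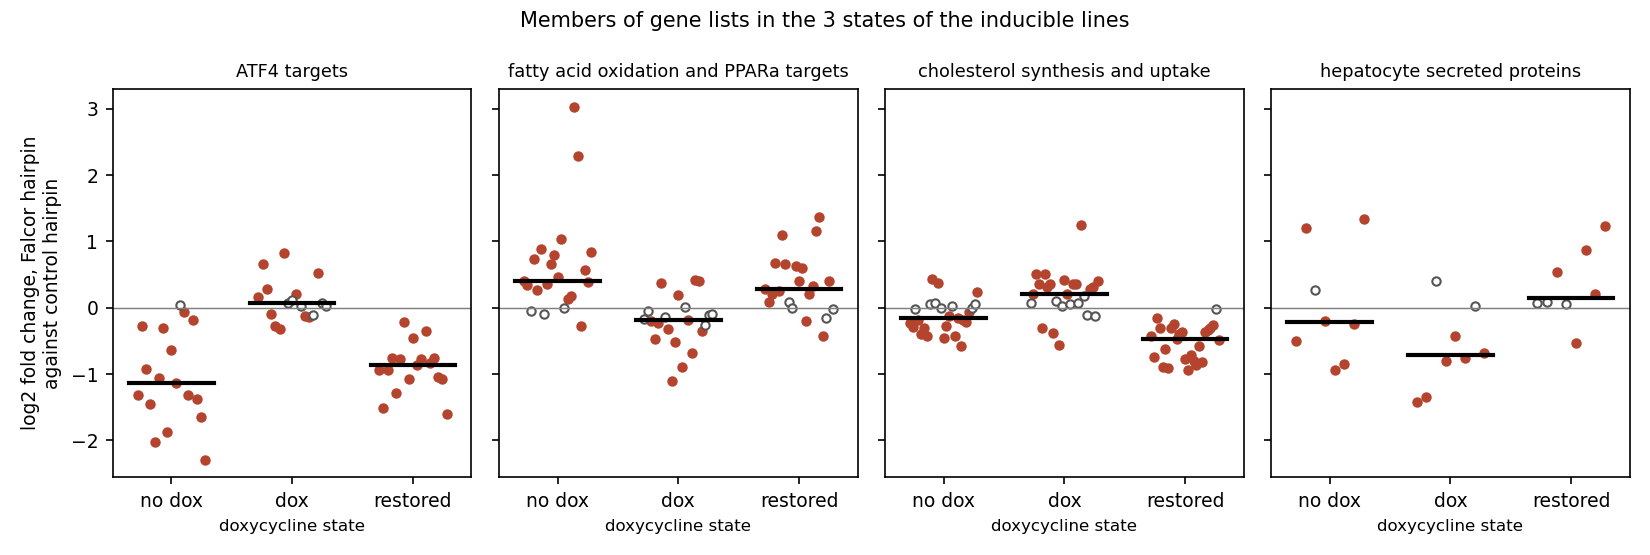
Log2 fold changes (Falcor hairpin against control hairpin) of the tested members of 4 gene lists without doxycycline, with doxycycline and in the restored state, with filled points for an adjusted p under 0.05, open points for others and bars for the list median. The ATF4 list medians lie at −1.13 without doxycycline and −0.87 in the restored state, and the secreted protein median lies at −0.72 with doxycycline.

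Subtracting the untreated from the doxycycline comparison gave the change of the hairpin difference under doxycycline, which can also hold a different response of each line to the drug. Relative to the untreated lines, ATF4 targets were higher and fat oxidation genes lower. Shmt2 changed by 1.90 ± 0.05, Mthfd2 by 1.93 ± 0.06, Asns by 1.47 and Atf5 by 1.35, and 14 of 17 ATF4 targets were higher and none lower, also when adjusted over the list alone (median 1.20, camera adjusted p = 1.66e-07, and adjusted p = 0.0106 with an estimated correlation). Of 21 fatty acid oxidation and PPARα targets, 18 were lower and none higher, also when adjusted over the list alone (median −0.58, camera adjusted p = 1.32e-06, and adjusted p = 0.00192 with an estimated correlation), with Angptl4 at −1.77, Acadm at −1.21 and Hadhb at −0.86. Limma called 6413 genes (3351 higher, 3062 lower). Falcor itself changed by −1.53 ± 0.20 (adjusted p = 4.27e-06), Zc3h11a by −0.32 ± 0.09 (adjusted p = 0.00733) and Foxa2 by 0.32 ± 0.05 (adjusted p = 2.73e-05, but 0.12 and adjusted p = 0.0590 with no rescaling). The largest increases were those of Ly6c1 (2.92 ± 0.25), Trib3 (2.32 ± 0.10), Cth (2.30) and Etv4 (2.27), and large decreases those of Isg20 (−3.35 ± 0.08), Mmp28 (−2.76), Akr1b7 (−2.74), Aspa (−2.73), the Wnt ligand Wnt4 (−2.59) and Apob, the apolipoprotein of very low density lipoprotein (−2.54 ± 0.41). Against the restored state, Falcor changed by −1.64 ± 0.20 and 5974 genes were called, 3132 higher and 2842 lower, with Ccn2 at 2.67 ± 0.04. Between the restored and untreated comparisons 1960 genes were called, with Falcor at 0.10 (limma adjusted p = 0.768).

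Of the 5172 genes called under doxycycline, 24.3% were called in the same direction in the restored state and 24.0% without doxycycline, below the 29.0% and 32.7% that independent lists would share. The opposite direction was called for 40.5% and 47.3%. The genes higher under doxycycline had a median of 0.30 there, −0.12 in the restored state and −0.17 without doxycycline, and the genes lower under doxycycline had medians of −0.39, 0.06 and 0.11. Fold changes also trended with transcript length, at a Spearman correlation of −0.14 with doxycycline, 0.28 in the restored state and 0.38 without doxycycline. How far this accounts for the opposite directions was not tested.

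Doxycycline in the control hairpin line was compared with no doxycycline, to ask what the drug and hairpin induction do without a Falcor hairpin. The states are separate groups of libraries, so other differences between their cultures cannot be told apart from the drug and induction. Lcn2 dropped from 617 ± 33.6 to 9.44 ± 0.0218 (log2 fold change −5.89 ± 0.03), haptoglobin mRNA by a log2 value of −4.45 (Hp), complement C3 from 241 to 11.2, Fos from 89.7 to 3.85 and Atf3 from 146 to 9.44. The serum amyloid gene Saa3, at 199 ± 25.7 untreated, and the chemokine gene Cxcl2, at 10.7, were listed at 0 with doxycycline. The proliferation antigen gene Mki67 rose from 12.9 to 55.6 (2.08 ± 0.17).

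Limma called 6565 genes (3354 higher, 3211 lower). Falcor did not pass (−0.06 ± 0.14, adjusted p = 0.737), Foxa2 fell (−0.19 ± 0.03, adjusted p = 1.32e-04) and Zc3h11a rose (0.26 ± 0.07, adjusted p = 0.00247). Other large increases were those of Prl2c2 (3.00), Prl2c3 (2.49), Tll1 (2.28), Gsta1 (1.99), Igfbp3 (1.93), Apob (1.83) and the nuclear pore gene Tpr (1.83). All 14 tested NF-κB targets fell, also when adjusted over the list alone (median −1.72, camera adjusted p = 1.31e-11, and adjusted p = 1.33e-04 with an estimated correlation), with Cxcl5 at −3.02, Cxcl1 at −2.80 and Icam1 at −2.75. Of 13 immediate early genes 12 fell and 1 rose (median −1.61, camera adjusted p = 3.82e-08, and adjusted p = 4.78e-04 with an estimated correlation), with Egr1 at −2.60 and Jun at −1.81. Acute phase genes fell in 7 of 11 cases and rose in 1 (median −0.65, camera adjusted p = 9.82e-04, and adjusted p = 0.0105 with an estimated correlation). These counts were the same when adjusted over the list alone. Of 15 unfolded protein response genes 12 fell and 2 rose (13 and 2 adjusted over the list alone; median −0.69, camera adjusted p = 2.04e-05, and adjusted p = 0.00231 with an estimated correlation), led by Herpud1 (−1.09), Pdia4 (−0.82), Calr (−0.75) and the chaperone gene Hspa5 (−0.71). The speckle and splicing factor list rose in 22 of 33 cases and fell in 3, the same when adjusted over the list alone (median 0.38, camera adjusted p = 6.62e-04, and adjusted p = 0.00715 with an estimated correlation), with Sf3b1 at 1.06, Pnn at 0.94, Srsf3 at 0.86 and Srsf1 at 0.64.

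The conventional Falcor hairpin addressed the same depletion without doxycycline. In this experiment each target had a single group of hairpin libraries, so effects of a hairpin beyond its target cannot be told apart from the depletion. Foxa2, the neighbour of Falcor, was at 34.2 ± 2.43 CPM against 96.1 ± 5.97 CPM (n = 3 each; log2 fold change −1.48 ± 0.10, edgeR adjusted p = 1.89e-09), and Hnf4a, a nuclear receptor that maintains hepatocyte differentiation, at 60.1 ± 1.72 against 126 ± 2.11 CPM (−1.07 ± 0.08). Under the ZC3H11A hairpin Falcor fell by a like amount (−2.17), yet Foxa2 did not pass (0.11, edgeR adjusted p = 0.386) and Hnf4a rose (0.68). The falls of Foxa2 and Hnf4a thus did not track the Falcor level across these hairpins, of which the ZC3H11A hairpin also depletes Zc3h11a. Transthyretin mRNA was at 2.94 ± 2.17 against 131 ± 19.5 CPM (Ttr, −5.29 ± 0.32) and albumin mRNA at 11.1 ± 0.990 against 57.3 ± 3.91 CPM (Alb, −2.35 ± 0.14). The splicing factor gene Srsf3 rose from 1.49 ± 1.33 to 29.6 ± 6.61 CPM (4.31 ± 0.36, edgeR adjusted p = 1.22e-07).

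Of 11871 genes tested, edgeR called 6111, 3024 higher and 3087 lower, with a median absolute log2 fold change of 0.698. BC037704 had 0 counts in all controls and 6.42 ± 1.99 CPM with the hairpin, a call lost without Falcor hairpin replicate 1 or 2 (adjusted p = 0.0633 and 0.0540). Other large increases were those of Card14 (6.44 ± 0.68), the chitinase-like gene Chil1 (5.75 ± 0.54), Bdh2 (4.97), the macrophage marker Cd68 (3.65 ± 0.20) and Usp29 (3.59). Large decreases were those of the transporter Slco1a6 (−5.88 ± 0.47), the water channel Aqp1 (−5.28), the α1-antitrypsin genes Serpina1b (−4.81) and Serpina1a (−4.41 ± 0.45), which are near-identical copies and so uncertain, Cybb (−4.35) and Apoa1 of high density lipoprotein (−4.04 ± 0.69). Zc3h11a was at 37.5 ± 4.51 against 63.6 ± 4.36 CPM (−0.75 ± 0.24, adjusted p = 0.0243). That call was lost with no rescaling between libraries (−0.61, adjusted p = 0.0555), without control replicate 1 or 2 (adjusted p = 0.0698 and 0.0718) and without Falcor hairpin replicate 1, 2 or 3 (0.0659, 0.0790 and 0.0504).

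Of 9 tested hepatocyte secreted protein genes, 7 fell and 1 rose, the same when adjusted over the list alone (median −2.19, camera adjusted p = 7.19e-06, but adjusted p = 0.250 with an estimated correlation), with Hpx at −2.19 and the iron carrier transferrin gene Trf at −1.29. Hepatocyte transcription factors fell in 10 of 15 cases and rose in 1, the same when adjusted over the list alone (median −0.67, camera adjusted p = 0.00386, but adjusted p = 0.324 with an estimated correlation), with Prox1 at −0.93 and Cebpb at −0.78 beside Foxa2 and Hnf4a. Of 13 immediate early genes 11 fell and 1 rose (11 and 2 adjusted over the list alone; median −1.15, camera adjusted p = 1.42e-07, but adjusted p = 0.250 with an estimated correlation), with the MAP kinase phosphatase gene Dusp1 at −2.94, Zfp36 at −1.69, Ier2 at −1.33 and Fos at −1.17. The speckle and splicing factor list did not pass, with 16 of 34 members lower and 5 higher (16 and 6 adjusted over the list alone; median −0.20, camera adjusted p = 0.733). Srrm2, a scaffold of nuclear speckles, rose by 1.39 ± 0.08, whereas Nktr and Sf3b1 fell by 0.94 and 0.65.

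Depletion of ZC3H11A asked which genes depend on the protein partner. The acyl-CoA thioesterase gene Acot2 was at 14.8 ± 0.847 against 54.3 ± 4.05 CPM and Acaa2, of the last step of β-oxidation, at 50.7 against 132 CPM (−1.38). Atf5 was at 16.9 ± 0.474 against 82.6 ± 6.59 CPM (−2.29 ± 0.11). The epidermal envelope gene Ivl rose from 1.03 to 40.7 CPM (5.33 ± 0.32) and the lysosomal peptidase gene Prcp from 4.68 to 79.2 CPM (4.04 ± 0.16). Foxa2 was at 103 ± 14.1 against 96.1 ± 5.97 CPM, a difference that did not pass (0.11 ± 0.10, edgeR adjusted p = 0.386).

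EdgeR called 5757 genes (2867 higher, 2890 lower), with a median absolute log2 fold change of 0.690. Hsd17b14 had 0 counts with the hairpin and 6.06 CPM in controls. Other large decreases were those of Slco1a6 (−5.42), Ugt2b36 (−4.27), Dhodh of pyrimidine synthesis (−4.19), Ggt1 (−4.06), Fuom (−4.03) and Cxcl5 (−3.94 ± 0.13). Other large increases were those of Cd80 (5.28), Dock10 (4.88), H2-M9 (4.17), Vmn2r79 (4.01), Espl1 (3.85) and Tlcd3a (3.79 ± 0.21). Fatty acid oxidation and PPARα targets fell in 15 of 21 cases and rose in 3 (16 and 4 adjusted over the list alone; median −0.78, camera adjusted p = 1.91e-06, but adjusted p = 0.124 with an estimated correlation), among them Acot1 (−1.15). Of 19 ATF4 targets 14 fell and 1 rose, the same when adjusted over the list alone (median −0.42, camera adjusted p = 4.40e-04, but adjusted p = 0.115 with an estimated correlation), among them Trib3 (−1.42), Gdf15 (−1.16) and the amino acid transporter gene Slc7a5 (−1.13). The speckle list did not pass, with 10 of 34 members lower and 5 higher, the same when adjusted over the list alone (median −0.16, camera p = 0.354 before adjustment, and adjusted p = 0.882 with an estimated correlation). Among them Srrm1 (−0.48), Nktr (−0.74) and Srsf5 (−0.63) fell and the kinase gene Cdk12 (0.53) rose. Nor did the TREX list, of which ZC3H11A is a member, with 2 of 16 genes higher and 4 lower (2 and 3 adjusted over the list alone; median 0.07 and mean −0.01, camera adjusted p = 0.945). Zc3h11a, the target of the hairpin, at −3.03, is part of these values, and the list was not tested without it. Thoc5 rose by 0.82 and Ddx39a by 0.92, and Poldip3 fell by 0.27.

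The Falcor and ZC3H11A hairpins were also set directly against each other. Apoa1 was at 0.322 ± 0.287 CPM under the Falcor hairpin and 44.5 ± 20.8 CPM under the ZC3H11A hairpin (−6.92 ± 0.55), and Serpina1a at 1.87 ± 0.358 against 186 ± 66.2 CPM (−6.64 ± 0.40). Against controls, Apoa1, Serpina1a, Apob and Hnf4a fell with the Falcor hairpin and rose with the ZC3H11A hairpin, by 2.87 ± 0.35, 2.23 ± 0.26, 1.48 ± 0.10 and 0.68 ± 0.07. Foxa2 was lower under the Falcor hairpin (−1.59 ± 0.10, edgeR adjusted p = 5.01e-10). EdgeR called 6760 genes (3368 higher, 3392 lower), among them Sting1 (6.04), Cyb5r1 (5.98), Chil1 (5.84), the complement protease gene C1s1 (5.74 ± 0.26) and Upk3b (5.47) on the higher side and Serpina1b (−6.62), Ivl (−6.61), H2-M9 (−6.12) and Ccn5 (−5.86) on the lower. Falcor did not differ by the test (0.10 ± 0.62, adjusted p = 0.904), and Zc3h11a was higher under the Falcor hairpin (2.28 ± 0.30). Immediate early genes were lower under the Falcor hairpin in 12 of 13 cases and higher in none, also when adjusted over the list alone (median −1.43, camera adjusted p = 4.13e-11, but adjusted p = 0.128 with an estimated correlation), with Dusp1 at −3.95, Zfp36 at −1.93, Fos at −1.69 and Junb at −1.45. Secreted protein genes were lower in 7 of 9 cases and higher in 1 (8 and 1 adjusted over the list alone; median −1.12, camera adjusted p = 8.40e-05, but adjusted p = 0.330 with an estimated correlation).

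Joint regulation by Falcor and ZC3H11A was addressed by the overlap of both knockdowns. Falcor itself fell under both hairpins (−2.07 and −2.17), so joint regulation and the loss of Falcor in both arms cannot be told apart. Slco1a6, Cxcl5, Aqp1, Ttr and albumin mRNA fell under both hairpins, with Aqp1 at −5.28 and −3.10, Cxcl5 at −2.52 and −3.94, and Ttr at −5.29 and −1.48. Of 11871 genes, 1223 rose under both and 1205 fell under both, against 730 and 752 from independent lists, and 1180 were called in opposite directions. Unchanged groups and controls, all drawn from the control means, shared at most 1 gene in 50 simulations. No gene differs in such groups, so that count cannot show how far shared controls add to the overlap of called genes. Fold changes correlated at r = 0.27 across genes against 0.50 in the simulations, with a covariance of 0.195 against 0.044 (difference 0.152). The 3 control libraries were not divided between the knockdowns, so part of the excess may come from the shared controls. The splicing factor gene Srsf3, up under the Falcor hairpin, did not pass under the ZC3H11A hairpin (0.84, adjusted p = 0.156). The nuclear-retained RNA Malat1, chosen after its values were seen, fell under the Falcor hairpin (−1.40 ± 0.24, edgeR adjusted p = 0.00305) and was at −0.60 under the other (adjusted p = 0.0853). Neat1, another such RNA, was at −0.10 under the Falcor hairpin (adjusted p = 0.692) and rose under the ZC3H11A hairpin (1.28 ± 0.19, adjusted p = 0.00105).

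**Figure D3:**
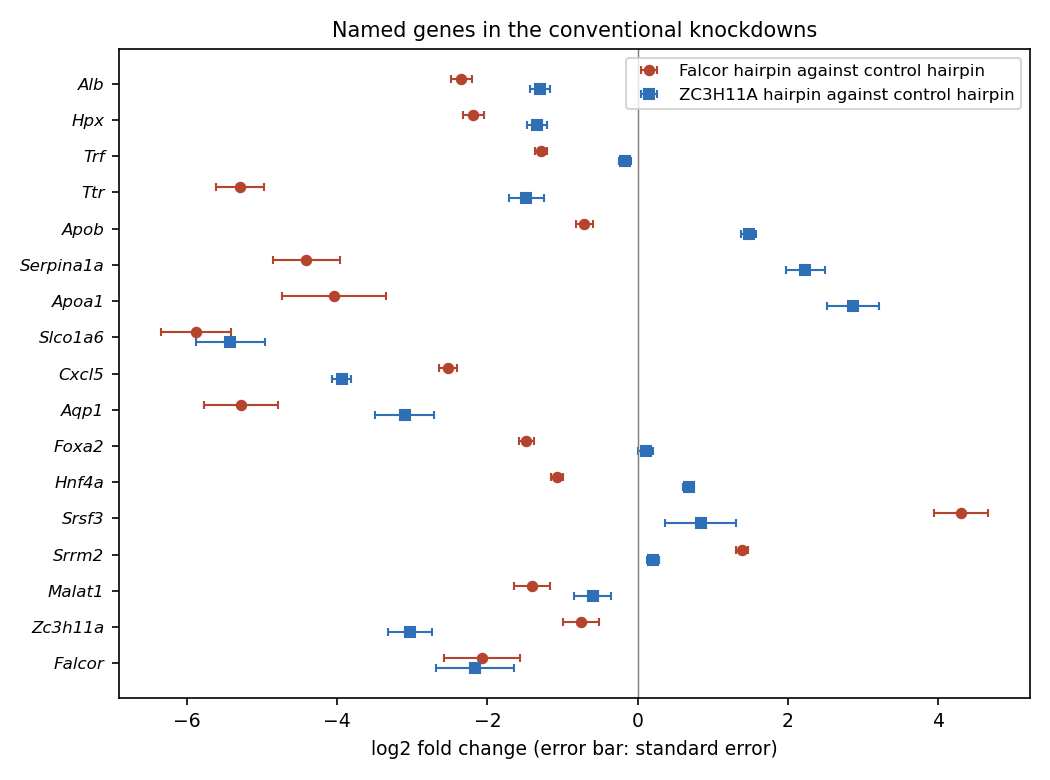
Log2 fold changes ± SE against the control hairpin of 17 genes in AML12 cells with the conventional Falcor hairpin and with the ZC3H11A hairpin (3 libraries per group). Slco1a6 lies at −5.88 and −5.42, whereas Apoa1 lies at −4.04 for Falcor and 2.87 for ZC3H11A.

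The inducible and conventional Falcor hairpins were compared through genes tested in both tables. Albumin, hemopexin and transthyretin mRNA fell in both, while Foxa2 rose slightly in the first (0.17) and fell in the second (−1.48), and Fos rose in the first (1.60) and fell in the second (−1.17). Of 9403 genes, 917 rose in both and 1121 fell in both, against 680 and 740 from independent lists (exact hypergeometric p = 1.95e-34 and 4.20e-81, one-sided), and 1002 were called in opposite directions. The correlation across genes was r = 0.22. These p-values treat genes as independent, which they are not.

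In livers on NCD, Falcor knockout asked about its role in normal physiology. The clock repressor gene Per1 was at 11.3 ± 2.28 against 3.46 ± 1.25 in controls (n = 4 each; log2 fold change 1.49 ± 0.21, limma adjusted p = 0.0314), Ciart, another clock repressor, at 8.46 ± 1.27 against 2.94 ± 0.994, and Tef, a clock-driven transcription factor, at 53.4 ± 4.99 against 33.8 ± 4.84. The glutathione transferase gene Gstm3 was at 54.5 ± 3.55 against 25.3 ± 7.21, and the cytochrome P450 gene Cyp2e1 at 4225 ± 319 against 2637 ± 369. Of the major urinary protein genes, which encode pheromone carriers, Mup15 was at 24.6 ± 19.9 against 982 ± 346 (−5.47 ± 0.49, adjusted p = 0.00690) and Mup17 at 22.6 against 506 (−4.43 ± 0.38), though copies of this family are near-identical and their values uncertain. Mup20, looked up after its value was seen, was at 0.58 (adjusted p = 0.121).

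Of 9536 genes tested limma called 570, 397 higher and 173 lower (2843 at an unadjusted p under 0.05), with a median absolute log2 fold change of 0.594. Library composition moved with the groups, as the 10 largest rows held 45.4 to 55.7% of each control total and 35.8 to 43.5% of each knockout total, and the scale factors were 0.88 to 0.97 and 1.00 to 1.15. Among abundant noncoding RNAs, picked after their values were seen, Rn7s1 was at 113696 to 189655 in controls and 76811 to 98531 in knockouts, and Rn18s-rs5 at 1225 to 1833 and 562 to 832, while the groups overlapped at Rn7sk (9639 to 12119 and 9368 to 10452) and Malat1 (3689 to 4237 and 3393 to 4099). How far this composition accounts for the calls was not tested. Other large increases were those of the mitochondrial mt-Atp8 (2.99 ± 0.62, 942 ± 858 against 110 ± 84.3), Snord15b (2.07), the steroid dehydrogenase gene Hsd17b6 (1.84 ± 0.23), Cr2 (1.80), Mir5124a (1.79), the uridine phosphorylase gene Upp2 (1.46 ± 0.27) and mt-Nd4l (1.40). Other decreases were those of Mup1 (−2.43), Mup12 (−2.26), Mup9 (−1.97), Mup2 (−1.76) and the small Cajal body RNAs Scarna2 (−1.48) and Scarna17 (−1.47). Foxa2 (−0.20 ± 0.22, adjusted p = 0.573) and Zc3h11a (0.05, adjusted p = 0.852) did not pass. The count depended on single libraries. It was 32 without control Ctrl-2, 9 without Ctrl-3, 6 without control replicate 3, 1707 without control replicate 4, and 7, 13, 9 and 7 without knockout replicates 1 to 4 in turn, so at most 6 of the genes named here keep their call when control replicate 3 is left out.

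Clock genes rose in 6 of 14 cases and fell in none (10 and 0 adjusted over the list alone; median 0.60, camera adjusted p = 1.24e-04, but adjusted p = 0.483 with an estimated correlation), among them Hlf (0.45). Xenobiotic metabolism genes rose in 4 of 15 cases and fell in none (13 and 0 adjusted over the list alone; median 0.46, camera adjusted p = 1.79e-05, but adjusted p = 0.902 with an estimated correlation), among them Gstm1 (0.85) and Cyp2a5 (1.36). Bile acid genes rose in 5 of 17 cases and fell in 1 (6 and 1 adjusted over the list alone; median 0.30, camera adjusted p = 0.0386, but adjusted p = 0.966 with an estimated correlation), with the uptake transporter genes Slco1b2 (0.64) and Slco1a1 (0.57) and the canalicular exporters Abcc2 (0.69) and Abcg5 (0.81). Of 13 mitochondrially encoded genes 6 rose and 1 fell (10 and 1 adjusted over the list alone; median 1.23, camera adjusted p = 0.00184, but adjusted p = 0.966 with an estimated correlation). Knockout replicate 4 stood above the other knockout livers at mt-Atp8 (2223 against 629 in the next), mt-Nd4l (3642 against 2048) and mt-Nd2 (717 against 415), and the list median was 0.98 without it. mt-Nd6, the one encoded on the light strand, fell by 1.16.

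On HFD, the knockout asked about the disease setting, and few single genes passed. Enho, which encodes the metabolic peptide adropin, was at 12.7 ± 3.00 in 6 knockout livers against 3.04 ± 1.28 in 5 controls (log2 fold change 1.81 ± 0.26, limma adjusted p = 0.0366), and Fkbp11, a prolyl isomerase of the endoplasmic reticulum, at 6.93 ± 0.770 against 3.27 ± 0.802 (0.91 ± 0.13, adjusted p = 0.0366). Together with Falcor these were the 3 genes called of 6176 (760 at an unadjusted p under 0.05). The count was 1 without control Ctrl-2, control replicate 3 or knockout replicates 3, 4 or 6, 5 without control Ctrl-1 and 8 without knockout replicate 2. Enho kept its call only when Ctrl-1 or knockout replicate 2 was left out, and Fkbp11 when those, control replicate 4 or knockout replicate 5 were. Foxa2 did not pass (0.24 ± 0.35, adjusted p = 0.823), and Zc3h11a was too low to be tested. Knockout replicate 6 stood apart in its scaling, with a factor of 0.438 and 78.2% of its total in 3 identical rows.

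Unfolded protein response genes leaned higher as a group, with a median of 0.48 over 15 members. By limma none passed over all genes and 11 were higher when adjusted over the list alone (camera adjusted p = 5.31e-11, but adjusted p = 0.307 with an estimated correlation). The chaperone gene Hyou1 was at 56.0 ± 7.27 against 35.1 ± 5.74 (0.66 ± 0.13, adjusted p = 0.0927), the secreted factor gene Manf at 63.7 ± 8.40 against 35.5 ± 8.74 (0.85, adjusted p = 0.102), and Pdia4 and Pdia6 at 0.54 and 0.43 (adjusted p = 0.144 each). Of 18 acute phase genes none passed over all genes and 3 were higher when adjusted over the list alone (median 0.82, camera adjusted p = 2.90e-07, but adjusted p = 0.363 with an estimated correlation). Saa3 was at 1.03 (adjusted p = 0.0735), Itih4 at 0.95 (adjusted p = 0.186) and Lbp at 0.92 (adjusted p = 0.145). Knockout replicate 1 held 3640 for Saa2, against 294 in the next knockout liver, and 44.2 for Lbp, against 28.3, and the list median was 0.44 without it. Fatty acid and triglyceride synthesis genes leaned lower, with none of 19 past the test over all genes and 2 lower when adjusted over the list alone (median −0.52, camera adjusted p = 2.20e-07, but adjusted p = 0.363 with an estimated correlation). Thrsp was at −1.61 (adjusted p = 0.102) and Srebf1, the regulator of lipogenesis, at 7.41 ± 1.15 against 15.4 ± 5.14 (adjusted p = 0.105). Pklr was at −0.54 and Fads2 at −0.63 (adjusted p = 0.293 and 0.298).

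**Figure D4:**
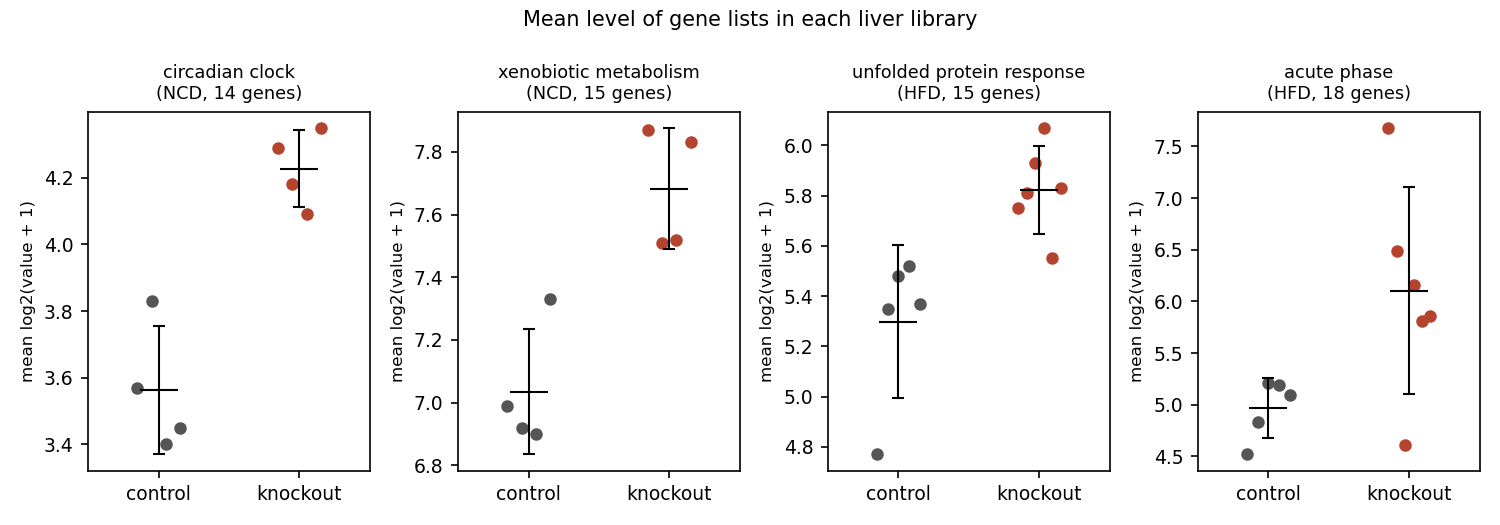
Mean log2(value + 1) over the members of a gene list in each liver, for the clock and xenobiotic lists on NCD and the unfolded protein response and acute phase lists on HFD, with points for livers and bars for mean ± SD. All 6 HFD knockout livers lie between 5.55 and 6.07 on the unfolded protein response list and the controls between 4.77 and 5.52.

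Whether the knockout effect differed between the diets was tested as the HFD minus the NCD effect. Each diet is a separate table, so any other difference between the sets of livers cannot be told apart from diet. Of the genes raised on NCD, differences that passed included −1.72 for Per1, −1.85 for Ciart, −0.83 for Tef, −2.06 for Upp2, −1.06 for Abcc2 and −0.72 for Slco1b2, whereas Slco1a1 did not differ by the test (−0.49, adjusted p = 0.135). In the other direction, Hyou1 (1.10), Manf (0.92), Lbp (1.15) and Itih4 (1.06) had the larger effect on HFD. The genes on each side were named for their effect on 1 diet, and the difference uses the same livers, so the choice favoured its sign. Of 6128 genes tested in both, 437 differed by this test (154 higher, 283 lower, 1791 at an unadjusted p under 0.05). Falcor is among them (2.28, adjusted p = 1.14e-05), which the design fixes, as it is deleted on both diets and the controls' levels differ. The count was 66 without NCD control Ctrl-2 or control replicate 3, 74 without Ctrl-3, 1169 without control replicate 4, 71, 236 and 77 without NCD knockout replicates 1, 2 and 4, and 259 without HFD control Ctrl-1. It was 51 with no rescaling between libraries, 230 with no filter and 955 with library weights. Fold changes on the 2 diets correlated at r = 0.02 across genes, and the 1 gene called on both was Falcor, the gene deleted in both.

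The conventional knockdown and the livers shared few genes. Of 7495 genes tested in the cells and on NCD, 67 rose and 37 fell in both, against 81.0 and 37.4 from independent lists (exact hypergeometric p = 0.975 and 0.563, one-sided), and 163 were called in opposite directions. The opposite calls were not set against a count from independent lists, so a lean to opposite directions was not tested. Fold changes correlated at r = −0.06 across genes. Falcor, targeted in both, is 1 of the 37. With HFD, 2 genes were shared, Falcor again and Enho, so the design fixes 1 of them.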

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

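The test for leakage of the Falcor hairpin was chosen only after the result it bears on was seen, as were the fits with no rescaling, with library weights and with the length trend removed, and the medians with single livers left out.

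The inducible lines differed before doxycycline, with 6445 genes called by limma. Leakage of the Falcor hairpin would lower Falcor in the untreated Falcor hairpin line, and Falcor was higher there than in the control line by 0.75 on the log2 scale. The level of that line without its hairpin was not measured, so the comparison with another line cannot decide on leakage. The untreated control replicate 1 had a scale factor of 0.91 and its group the widest spread of the inducible groups (median coefficient of variation 7.06%), but 6461 genes were called without it. The fold changes rose with transcript length (Spearman 0.38 across genes), and after removal of that trend 6185 genes were called against 6296 before, among 9582 genes with a length, so length does not account for the whole pattern. Other comparisons of these lines had trends too, at −0.14 with doxycycline, 0.28 in the restored state and 0.28 for doxycycline in the control line. The trend was −0.34 for doxycycline minus none and −0.28 for doxycycline minus restored. It was removed only for the untreated comparison, so its part in the others was not tested. A stable difference between separately derived lines stays open as a hypothesis, and so do leakage and an effect of the higher Falcor level, since the design holds 1 line per hairpin.

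The clock list leaned higher in the NCD knockout livers (camera adjusted p = 1.24e-04, but adjusted p = 0.483 with an estimated correlation). If the groups of livers differed in clock phase, Arntl, Npas2 and Cry1, whose rhythms oppose those of Per1 and Ciart, could be lower. Their mean values over all NCD livers were 2.58, 0.131 and 2.37, under the filter of 3, so they were read from the fit with no filter. There their median log2 fold change was −0.26, with Arntl at −0.96 ± 0.25 (limma adjusted p = 0.0796), Npas2 at −0.26 and Cry1 at −0.03. These genes lie near the detection floor, with Arntl at 1.40 against 3.76, so a difference in the time of sampling and an effect of the knockout cannot be told apart here. A single liver does not carry the list, whose median was at least 0.55 with any of the 8 livers left out, against 0.60 with all.

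The unfolded protein response and acute phase lists leaned higher in the HFD knockout livers. Knockout replicate 6, whose total is mostly 3 identical rows, does not account for the first, whose median was 0.46 without it against 0.48 with it. For the acute phase list, 5 of 6 knockout livers lay above the highest control, so more than a few livers showed it, yet its median fell from 0.82 to 0.44 without knockout replicate 1. An effect of the knockout under this diet remains a hypothesis, since no gene of either list passed limma's test over all genes and both list calls were lost with an estimated correlation. Inflammation in some animals for other reasons was not tested.

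Of 100 groups of values of named genes and scale factors, 9 held a library far from the rest, where chance gives about 1 in 20. On NCD these were Foxa2 in control Ctrl-2 (12.5, the lowest), Mir5124a in control replicate 4 (28.3, next 12.8), Gstm3 in knockout replicate 1 (59.8, next 53.2), and mt-Atp8 (2223, next 629), mt-Nd4l (3642, next 2048) and mt-Nd2 (717, next 415) in knockout replicate 4. On HFD they were Saa2 (3640, next 294) and Lbp (44.2, next 28.3) in knockout replicate 1 and the scale factor of knockout replicate 6 (0.438, next 1.02).

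The hairpin effect differed between doxycycline and no doxycycline at 6413 genes by limma's test of the difference. The log2 differences were −1.53 for Falcor, 0.32 for Foxa2, −0.32 for Zc3h11a, 2.92 for Ly6c1, 2.32 for Trib3, 2.30 for Cth, 2.27 for Etv4, 2.23 for Snora78, 2.17 for Snora73b, 2.14 for Trmt61a and 2.12 for Tnnt2. They were −3.35 for Isg20, −2.76 for Mmp28, −2.74 for Akr1b7, −2.73 for Aspa, −2.59 for Wnt4 and −2.54 for Apob. Snora73b lost its call when any of 12 of the 18 libraries was left out, among them untreated Falcor hairpin replicate 2 (1.55, adjusted p = 0.123). It also lost it with no filter (adjusted p = 0.0681), the filter on a value of at least 1 (0.0589), either pseudocount (0.0504 and 0.0655), library weights (0.0681) and no rescaling (0.0668). Between doxycycline and the restored state 5974 genes differed, with Falcor at −1.64 and Zc3h11a at −0.51, and between the restored and untreated states 1960, with Foxa2 at 0.21.

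The knockout effect differed between the diets at 437 genes, where diet cannot be told apart from other differences between the sets of livers. As the HFD minus the NCD effect, the log2 differences were −1.72 for Per1, −1.85 for Ciart, −0.83 for Tef, −2.06 for Upp2, −1.06 for Abcc2, −0.72 for Slco1b2, −1.12 for Abcg5, −0.66 for Cyp2e1, −1.55 for Cyp2a5, −1.44 for Hsd17b6, −2.70 for Snord15b, −1.31 for mt-Nd2, −1.58 for mt-Nd4l and −3.10 for mt-Atp8. They were 4.43 for Mup15, 3.03 for Mup17, 1.64 for Scarna2, 1.30 for Scarna17, 1.10 for Hyou1, 0.92 for Manf, 1.15 for Lbp and 1.06 for Itih4.

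Other splits of the same libraries were counted for each comparison. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split and the highest other called 5172 and 1 genes with doxycycline, 6445 and 1 without it, 5718 and 0 in the restored state, 6565 and 2 for doxycycline in the control line, 7329 and 0 for doxycycline in the Falcor hairpin line, 6111 and 0 for the conventional Falcor hairpin, 5757 and 0 for the ZC3H11A hairpin, and 6760 and 1 between these hairpins. Chance was excluded for NCD (1 of 35 splits, 570 against 2). For the difference between doxycycline and no doxycycline, the real split called the most genes (1 of 100 splits, 6413 against at most 5352). The real split also did between doxycycline and the restored state (1 of 100, 5974 against 3159) and between diets (1 of 100, 437 against 250). Splits of a difference shuffle the labels within each state or diet, so they assume no hairpin or knockout effect in either. Such splits cannot show that the effects differ. On HFD 3 of 100 splits called as many as the 3 genes, which include the deleted Falcor, and the highest called 24. Falcor's own call is fixed by the design, so genes other than Falcor were counted too, a test chosen after the result was seen. That gave 1 of 35 splits on NCD (569 against 2) and 3 of 100 on HFD (2 against 24). The HFD share is under 0.05, but it rests on 2 genes. Both lost their call with DESeq2's size factors and in most fits with a liver left out, so chance is not taken as excluded for them. For the restored against the untreated state, 10 of 100 splits called as many as 1960 and the highest 7057. This decides nothing, because both states share a large hairpin difference (4504 genes called the same way), which a split of 1 state alone carries into the comparison. On HFD another split called several times the real count, at 24 against 3, and no test identified why.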

How the results depend on the processing

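The fits with a pseudocount of 0.5 or 5, a mean of at least 10, library weights or no rescaling were chosen after the data were seen, the others before. The cause of the changes below was not tested. Across 20 alternatives, named genes kept direction and call in 3424 values, while 32 lost and 9 gained a call and 5 reversed. With single libraries left out 4747 were kept, 229 lost, 1 gained and 3 reversed. These counts exclude Falcor and Zc3h11a where they were the targets. There the alternatives kept 146 values and lost 3, and single libraries left out kept 208, lost 5 and reversed 4. Every count of called genes in the cell lines stayed within 1.5 times. A DESeq2 Wald test of the counts called 5560 genes for the Falcor hairpin, 5179 for ZC3H11A and 6269 between them. It was not run for the other tables, which hold no counts. Neither the planned joint fit of both diets nor a division of the 3 conventional controls was run.

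Of the named targets, Zc3h11a under the conventional Falcor hairpin was at −0.61 with no rescaling, and between −0.82 and −0.66 with single libraries left out. Without doxycycline, Zc3h11a turned to 0.01 with library weights and 0.12 with no rescaling. With no rescaling Foxa2 turned to 0.05 without doxycycline, to −0.06 in doxycycline against the restored state, and to −0.08 for doxycycline in the Falcor hairpin line. With single libraries left out, Falcor ranged from −0.15 to 0.04 for doxycycline in the control line and from −0.19 to 0.43 between the conventional hairpins, Foxa2 from −0.00 to 0.18 under the ZC3H11A hairpin, and Zc3h11a from −0.07 to 0.20 on NCD. None of these values passed the test with all libraries except Foxa2 without doxycycline and in the Falcor hairpin line and Zc3h11a under the conventional Falcor hairpin.

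The 570 genes on NCD became 1610 with library weights and 1746 with no rescaling, and 6 to 1707 with single livers left out. With no filter mt-Atp8, Cr2, mt-Nd4l, Scarna2, mt-Nd6 and Cyp2a5 lost their call there (limma adjusted p = 0.0596 to 0.0750). With a value of at least 1 in as many libraries as the smallest group, these except mt-Atp8 lost it and so did Abcg5 (0.0504 to 0.0566), as did Cyp2a5 with DESeq2's size factors (0.0518). The 3 genes on HFD became 1 with DESeq2's size factors, 12 with no filter, 10 with library weights, 29 with no rescaling, and 1 to 8 with single livers left out. With a mean of at least 10 limma called 0 of them (430 genes at an unadjusted p under 0.05), and Falcor had an adjusted p of 0.0780, against 3.60e-09 in the fit reported and at most 4.05e-07 with single livers left out. The 437 genes that differed between diets became 230 with no filter, 252 with a value of at least 1 in as many libraries as the smallest group, 955 with library weights, 51 with no rescaling, and 66 to 1169 with single livers left out.

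No rescaling moved the median of all genes by over 0.1 and the share of higher calls by over 10 points in 8 comparisons. The share went from 46.2 to 67.6% without doxycycline (median shift 0.18), 44.5 to 67.2% in the restored state (0.15), 52.3 to 36.0% in doxycycline against none (−0.19), 52.4 to 36.7% in doxycycline against restored (−0.16), 52.0 to 35.9% for doxycycline in the Falcor hairpin line (−0.20), 49.5 to 62.5% for the conventional Falcor hairpin (0.15), 49.8 to 61.3% between both conventional hairpins (0.16) and 69.6 to 94.9% on NCD (0.17). On HFD it went from 66.7 to 44.8%.

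Of 313 list tests, camera called 104, fry 215 and camera with an estimated correlation 40. The TREX list under the ZC3H11A hairpin had the opposite direction by fry (adjusted p = 0.835). At an adjusted p under 0.01, the overlap of the conventional knockdown with NCD held 1 gene and with HFD 1 gene. When genes were selected from the difference between doxycycline and none, 7.13% were called the same way in the restored state and 2.92% without doxycycline. That selection subtracts the untreated comparison, so it lowers the share without doxycycline by itself. It can lower the restored share too, since the restored and untreated fold changes correlated at r = 0.74.

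No label says that the replicate numbers pair the libraries and no experiment with at least 3 pairs had all its correlations over 0.1, so the block is given only here. Correlations of same-numbered libraries ran from −0.14 to 0.14 in the inducible lines (45 pairs), −0.05 to 0.11 in the conventional lines (9), 0.03 to 0.12 on NCD (2), and −0.09 to 0.20 by title or −0.23 to −0.05 by description on HFD (3 each). Of the libraries, 9 of 18, 5 of 9, 3 of 6 and 0 of 6 correlated best with their own number, for the experiments with at least 3 pairs in that order. On NCD 4 of 4 did, with 2 pairs. With the replicate number as a block, Zc3h11a under the conventional Falcor hairpin was at −0.74 (edgeR adjusted p = 0.0567) and BC037704 there had an adjusted p of 0.0988, the Snora73b difference between doxycycline and none had a limma adjusted p of 0.0731, NCD gave 1161 genes by either numbering, HFD 1, and the difference between diets 752 by title and 723 by description.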

Other observations

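The gene lists and members given here were chosen after their values were seen, and the comparisons before. Doxycycline in the Falcor hairpin line, where Falcor fell from 9.39 to 2.45 (log2 fold change −1.59 ± 0.14, limma adjusted p = 1.84e-08) was compared with no doxycycline. The serum amyloid gene Saa3 dropped from 267 to 2.46 (−6.38 ± 0.23), complement C3 from 645 to 16.1 and the chemokine gene Cxcl5 from 504 to 19.3 (−4.64 ± 0.07). The spermidine synthase gene Srm rose from 22.7 to 153 (2.70 ± 0.05), Pprc1, a coactivator of mitochondrial biogenesis, from 11.5 to 71.9, and Igfbp3 rose to 24.9 (3.39 ± 0.12). Limma called 7329 genes, 3813 higher and 3516 lower. All 14 NF-κB targets tested fell, also when adjusted over the list alone (median −1.83, camera adjusted p = 4.76e-09, and adjusted p = 2.72e-04 with an estimated correlation). Of 21 fatty acid oxidation and PPARα targets 20 fell and none rose, also when adjusted over the list alone (median −0.95, camera adjusted p = 4.76e-09, and adjusted p = 2.72e-04 with an estimated correlation), with Pdk4 at −4.10 and Cpt1a, the gate of mitochondrial fat import, at −1.34. Proliferation genes rose in 22 of 23 cases and fell in 1, the same when adjusted over the list alone (median 0.95, camera adjusted p = 4.38e-08, and adjusted p = 0.00163 with an estimated correlation). Speckle and splicing factors rose in 24 of 33 cases and fell in 6 (25 and 6 adjusted over the list alone; median 0.48, camera adjusted p = 0.00149, and adjusted p = 0.00775 with an estimated correlation), with Srsf2 at 1.13 and U2af2 at 1.11. TREX genes rose in 11 of 15 cases and fell in none, also when adjusted over the list alone (median 0.46, camera adjusted p = 0.00329, and adjusted p = 0.0182 with an estimated correlation), with Ddx39a at 1.43 and Alyref at 0.95. With no rescaling the median of all genes shifted by −0.20.

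Between doxycycline and the restored state, the hairpin difference was higher under doxycycline for all 17 ATF4 targets tested, also when adjusted over the list alone (median 1.03, camera adjusted p = 3.20e-10, and adjusted p = 0.00301 with an estimated correlation). Cholesterol genes were higher in 21 of 25 cases and lower in none (22 and 1 adjusted over the list alone; median 0.67, camera adjusted p = 6.51e-09, and adjusted p = 0.00543 with an estimated correlation). Between the restored and untreated states, cholesterol genes were lower in 20 of 25 cases and higher in none (21 and 0 adjusted over the list alone; median −0.36, camera adjusted p = 8.60e-17, and adjusted p = 4.33e-04 with an estimated correlation). NF-κB targets were lower in 10 of 14 cases and higher in none, also when adjusted over the list alone (median −0.38, camera adjusted p = 1.59e-09, and adjusted p = 4.20e-04 with an estimated correlation), with Cxcl5 at −2.53 and Cxcl1 at −1.92. Haptoglobin mRNA differed by 2.22 ± 0.15 in the other direction (Hp).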
